A study of Homo sapiens with 9 samples.

How the data were processed

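Polyadenylated RNA from 786-O cells was sequenced, per the labels, on an Illumina NovaSeq instrument after library preparation with a directional kit. All 9 libraries carry the same batch label. The labels name the treatments as siRNA in some fields and as shRNA in another, and call the control both a negative control and parental, so the kind of reagent, and whether the controls were transfected, are uncertain here. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.6, STAR 2.7.9a, featureCounts 2.0.1, DESeq2 1.30.0 and R 4.0.3, with the GRCh38 build. The annotation release and the strand setting of the counting are not given in the sources used here.

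The authors deposited raw read counts per gene, whole numbers that were not normalized, per the file headers and the values. They also deposited FPKM values per gene, per the file headers. Each FPKM was the count times a constant over the summed exon length and the library total, and 0 values departed from this beyond rounding. The table lists 61806 genes, 20417 of them without a symbol, and gives no gene class. Total counts ran from 11963110 to 20224374 per library and genes detected from 17977 to 20116. Columns were matched to libraries by their names. Coordinates and summed exon lengths are those of the deposited table, and GC content from the reference annotation covered 13390 of the tested genes, 98.7%.

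Changes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test on the deposited counts with TMM factors and the package's filter on low counts, which left 13562 genes. The 9 libraries entered 1 fit with 3 groups and no covariates, leaving 6 residual degrees of freedom, and the biological coefficient of variation was 0.149. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05, and the stricter count asked also for an absolute log2 fold change of at least 1. CPM values are TMM-scaled, and log2 values for principal components used a prior count of 2. The design allowed for either unit and set this test for counts and limma on log2(FPKM + 1) otherwise, so limma became an alternative.

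Gene lists, 37 in number, were fixed with the tests, the naming rule and most alternatives before the data were examined. The 34 lists with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. No list call held with an estimated correlation, where 0 lists passed in any comparison by camera and 3, 3 and 0 had an unadjusted p below 0.05, against 14, 25 and 12 lists passing by fry. The naming rule took both targets, and for each knockdown the 8 largest rises and 8 largest falls among genes past the threshold with a mean FPKM of at least 1, a gene symbol and no overlap between the groups' libraries. For the direct comparison it took 5 in each direction. For genes past the threshold in both knockdowns it took up to 5 in each pair of directions, and for each list up to 3 members with the smallest adjusted p per direction, or the 1 with the smallest where none passed. Of 43 genes named by fold change, 12 overlap a tested gene, 7 of them on the opposite strand only.

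Alternatives planned in advance were DESeq2 1.42.0, its size factors, limma on FPKM with pseudocounts of 1, 0.1 and 0.01 and mean FPKM filters of 0.5 and 2 or none, other FPKM scalings, fits of the compared groups alone, a replicate block and leaving out each library. Fold changes from limma are on the log2(FPKM + pseudocount) scale and understate changes of low genes. Library totals without TMM factors, and the removal of length or length and GC trends from each library by lowess with a span of 0.3, were chosen after seeing the data. Pathways were taken from KEGG after the data were seen, 296 of them with 15 to 300 tested genes. Shared controls were simulated with 20 sets of unchanged groups. Figures and extracts were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

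The tests were run first on simulated counts for the comparison of TRIM28 knockdown with control, with 200 genes changed. Over 13562 genes edgeR recovered 23.9% of 1.5-fold, 67.2% of 2-fold and 89.4% of 4-fold changes with 10 false calls. DESeq2 recovered 25.4%, 64.2% and 89.4% with 21 false calls. Over 10854 genes limma recovered 10.4%, 59.7% and 77.3% with 8 false calls. On counts simulated with a length trend for the same comparison, removing the trend changed its slope from -0.101 to -0.00443 and the false calls from 31 to 8, with 64% and 61% of changed genes recovered. Replicates were checked for duplicated libraries, and each pair differed by more than sampling noise. Some members of the lists are not reported here. Genes without a symbol were tested but not named, apart from transcripts of the ribosomal DNA region.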

Results

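Messenger RNA was sequenced from 9 libraries of 786-O cells, a line derived from a human clear cell renal carcinoma that lacks functional VHL. The labels place 3 libraries in each of 3 groups: cells labelled as a negative control and elsewhere as parental, cells in which TRIM28 was silenced and cells in which PARP1 was silenced. TRIM28 is a corepressor that KRAB zinc finger proteins bring to chromatin, and PARP1 is a poly(ADP-ribose) polymerase that acts at DNA breaks. Each silencing was compared with control, to ask which transcripts change when either protein is depleted, and both silencings were compared with each other. Total counts per library ran from 11963110 in PARP1 knockdown replicate 3 to 20224374 in control replicate 3, and 13562 genes passed the filter on low counts. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Unless stated otherwise, a gene rose or fell when its adjusted p was below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and an error after a log2 fold change is its standard error with n = 3 libraries per group.

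TRIM28 (ENSG00000130726, chromosome 19, 58544064 to 58550722, plus strand, GRCh38) stood at 346 ± 33.0 CPM (SD, n = 3) in control and at 52.2 ± 7.34 CPM (SD, n = 3) in TRIM28 knockdown, 15.1% of the control mean. The 3 TRIM28 knockdown libraries held 44.0, 54.7 and 58.0 CPM of it, against 316, 342 and 381 CPM in control. PARP1 (ENSG00000143799, chromosome 1, 226360210 to 226408154, minus strand) stood at 177 ± 23.7 CPM (SD, n = 3) in control and at 5.52 ± 1.19 CPM (SD, n = 3) in PARP1 knockdown, 3.11% of the control mean. The PARP1 knockdown libraries held 6.82, 4.48 and 5.24 CPM of PARP1, against 178, 200 and 153 CPM in control. PARP1 was also lower in TRIM28 knockdown, at 93.8 ± 0.556 CPM (SD, n = 3) or 52.9% of control, a log2 fold change of -0.92 ± 0.14 (adjusted p = 3.61e-05, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Its summed exon length of 18399 bases puts PARP1 in the longest of 10 equal length classes of tested genes. That class had a median log2 fold change of -0.39 in TRIM28 knockdown, with 34.6% of its genes lower, so part of this fall may follow length. TRIM28 stood at 430 ± 9.96 CPM (SD, n = 3) in PARP1 knockdown, a log2 fold change of 0.31 ± 0.13 (adjusted p = 0.0433, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). That call ended without control replicate 1 (0.29), control replicate 2 (0.34) or PARP1 knockdown replicate 2 (0.33), and its sign turned with library totals in place of TMM factors (-0.01).

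**Figure D1:**
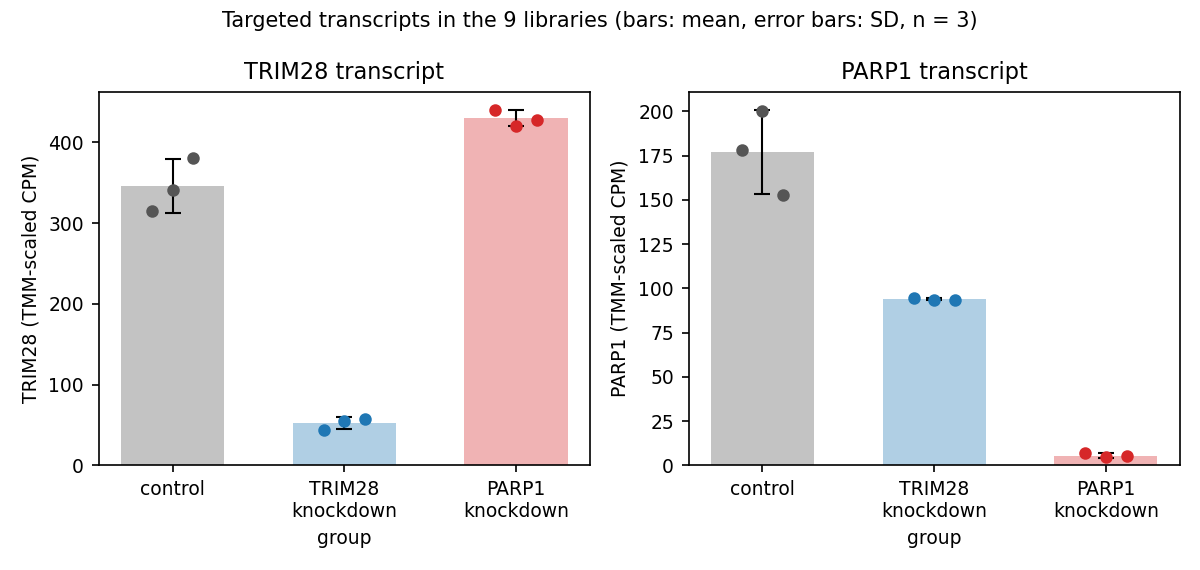
TMM-scaled CPM of TRIM28 (left) and PARP1 (right) in each of the 9 libraries; bars are group means, error bars the SD over 3 libraries and points single libraries. TRIM28 lay between 44.0 and 58.0 CPM in TRIM28 knockdown, and PARP1 between 4.48 and 6.82 CPM in PARP1 knockdown and between 93.3 and 94.4 CPM in TRIM28 knockdown.

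The libraries also differed in make-up. Genes of cytosolic ribosomal proteins took 11.6% ± 0.833 of the counts in control, 14.6% ± 0.929 in TRIM28 knockdown and 17.2% ± 2.18 in PARP1 knockdown (SD, n = 3). A chosen set of transcripts from the ribosomal DNA region, not all of those annotated there, took 0.309% ± 0.102, 0.783% ± 0.0577 and 1.89% ± 1.20 (SD, n = 3), with 3.11% in PARP1 knockdown replicate 2. Within each library the log2 level of a gene, set against its mean over all libraries, was related to its summed exon length. That slope per doubling of length was 0.115 ± 0.0488 in control, -0.013 ± 0.0229 in TRIM28 knockdown and -0.102 ± 0.0416 in PARP1 knockdown (SD, n = 3). Control replicate 3, at 0.06, lay nearer to the knockdowns than control replicates 1 and 2, at 0.153 and 0.132. The first principal component held 61.2% of the variance and put control replicates 1 to 3 at -64.1, -58.4 and -29.6, TRIM28 knockdown between -4.0 and 4.5 and PARP1 knockdown between 34.5 and 66.1.

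In TRIM28 knockdown, IFITM1, IFI27 and RTP4 were among the largest rises and HNRNPU, DHX9 and MCM3AP among the largest falls that the naming rule took. IFITM1, an interferon-induced membrane protein that restricts virus entry, rose 2.57-fold to 30.8 ± 1.95 CPM (SD, n = 3). IFI27, an interferon alpha-inducible gene, rose from 49.1 ± 4.28 to 117 ± 9.17 CPM (SD, n = 3), 2.39-fold, and RTP4, an interferon-induced receptor transporter, rose 2.24-fold from 1.39 ± 0.0365 CPM (SD, n = 3). HNRNPU, a nuclear matrix RNA-binding protein, fell from 382 ± 88.1 to 117 ± 5.93 CPM (SD, n = 3), and DHX9, an RNA and DNA helicase, fell from 55.5 ± 17.3 to 17.4 ± 1.99 CPM (SD, n = 3). MCM3AP, which acts in messenger RNA export, fell from 63.1 ± 3.67 to 16.4 ± 0.865 CPM (SD, n = 3), 3.85-fold, the largest of these falls after TRIM28 itself.

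The other named falls were CMTM4, a membrane protein that stabilises PD-L1 (log2 fold change -1.82 ± 0.24), CHRDL1, a secreted antagonist of bone morphogenetic proteins (-1.75 ± 0.17), LIMA1, an actin-binding protein (-1.67 ± 0.18), and TCF20, a transcriptional coregulator (-1.66 ± 0.22). U2AF1, a splicing factor subunit, had the highest named rise (1.45 ± 0.22), but the build holds a near-identical copy of it, so its counts are uncertain. MCM3AP, HNRNPU and TCF20 each overlap a tested gene on the opposite strand, and whether counting used strand is not given in the sources used here. The remaining rises taken by the rule, EEF1G, RHEBL1 and the pseudogenes RPL7AP30 and FAM207BP, lay between 1.23 and 3.25 CPM in TRIM28 knockdown. EEF1G lost its call without control replicate 2 (1.00) or TRIM28 knockdown replicate 2 (0.80), and RHEBL1 without control replicate 2 or 3 or TRIM28 knockdown replicate 2 or 3 (0.86 to 1.06). FAM207BP lost it without control replicate 1 or 2 or TRIM28 knockdown replicate 1 or 2 (1.07 to 1.15), and RPL7AP30 without control replicate 1 or 2 or any single TRIM28 knockdown replicate (1.02 to 1.47). EEF1G overlaps a tested gene on its own strand, and pseudogenes can share reads with their parent genes.

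Against control, 3768 of the 13562 genes passed in TRIM28 knockdown, 1394 higher and 2374 lower, and 51 rose and 760 fell at least 2-fold. With library totals in place of TMM factors, chosen after seeing the data, 453 were higher and 2856 lower, limma on the deposited FPKM gave 541 and 2162, and limma on TMM-rescaled FPKM gave 673 and 1984. Removing the gene length trend of each library, also chosen after seeing the data, gave 1566 higher and 1671 lower, and removing length and GC trends gave 1505 and 1439. Relative to the TMM scale, library totals shifted the median of all genes by -0.16 in TRIM28 knockdown and -0.33 in PARP1 knockdown. Fold change fell with exon length across genes, which are not independent replicates (Spearman rho = -0.414), from a median of 0.33 in the shortest of 10 equal length classes to -0.39 in the longest. The count was 1537 without control replicate 1, 1855 without control replicate 2 and 2116 without TRIM28 knockdown replicate 2. Each of these 3 fits had more falls than rises.

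Among interferon-stimulated genes, 17 of 45 measured members rose, 6 fell and 22 did not pass in TRIM28 knockdown (17 and 8 adjusted over the list alone). OASL, an antiviral protein related to oligoadenylate synthetases, rose by a log2 fold change of 1.03 ± 0.13 alongside IFITM1 (1.36 ± 0.18) and IFI27 (1.26 ± 0.16). Members that fell included the partners DTX3L (-1.13 ± 0.25) and PARP9 (-1.14 ± 0.27). The list as a whole was higher than other genes (median log2 fold change 0.28, camera adjusted p = 5e-04), with adjusted p = 0.539 with an estimated correlation. The median exon length of its members was 5659 bases.

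Ribosomal protein genes rose together: 60 of 81 rose and 21 did not pass in TRIM28 knockdown (69 higher and 1 lower adjusted over the list alone). RPL18 rose by 0.66 ± 0.14 and RPS9 by 0.64 ± 0.15 on the log2 scale. The list median was 0.48 (camera adjusted p = 3.01e-18), and adjusted p = 0.563 with an estimated correlation. Nuclear genes of oxidative phosphorylation did likewise, 28 of 42 rising, 1 falling and 13 not passing (33 and 1 adjusted over the list alone), with NDUFB8 of complex I at 0.73 ± 0.15 and SDHC of complex II at 0.54 ± 0.13. NDUFS1, a complex I subunit, was the member that fell (-0.79 ± 0.16), a call that ended with length and GC trends removed (-0.28). The list's camera adjusted p was 2.11e-09, and adjusted p = 0.563 with an estimated correlation. Histone genes, whose transcripts are short (median exon length 496.5 bases), had 4 of 54 members higher and 50 not passing (0 adjusted over the list alone by edgeR, with 13 at an unadjusted p below 0.05) and a median of 0.22 (camera adjusted p = 0.0144, and adjusted p = 0.644 with an estimated correlation). With the length trend removed the histone median was -0.05 (camera adjusted p = 0.565), with length and GC trends removed -0.12, and without TRIM28 knockdown replicate 2 it was 0.17 (camera adjusted p = 0.132). The ribosomal share of counts and the length slope of the libraries, given above, moved with these lists.

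Genes of TRIM28 partners and heterochromatin fell in TRIM28 knockdown, 14 of 30 lower and 16 not passing (1 higher and 15 lower adjusted over the list alone). Besides TRIM28, CHD3, a helicase of the NuRD complex, fell by 1.24 on the log2 scale (SE 0.14), and MORC2, an ATPase that acts with the HUSH complex, fell by 1.41 (SE 0.17). The list holds TRIM28 itself and its genes are long (median exon length 9452.5 bases). Its median was -0.45 (camera adjusted p = 2.16e-07), and adjusted p = 0.477 with an estimated correlation. Heat shock genes had 8 of 18 members lower and 10 not passing (1 higher and 9 lower adjusted over the list alone), among them the chaperones HSPD1 (-1.27 ± 0.15), HSP90AB1 (-1.08 ± 0.15) and HSPA4 (-1.27 ± 0.18). That list had a median of -0.40 (camera adjusted p = 0.0037, and adjusted p = 0.477 with an estimated correlation).

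Of the proximal tubule and renal epithelial genes, 7 of 15 were lower and 8 did not pass in TRIM28 knockdown (7 lower adjusted over the list alone). They included the cadherin CDH6 (-1.08 ± 0.16), the injury marker HAVCR1 (-1.08 ± 0.18) and the adhesion molecule VCAM1 (-0.86 ± 0.16). The median was -0.36 (camera adjusted p = 0.0188, and adjusted p = 0.563 with an estimated correlation), and the call ended with the length trend removed (-0.10, camera adjusted p = 0.121) and with limma on the deposited FPKM (0.0576), but not with length and GC trends removed (-0.26, 0.0118). Of 46 DNA replication and G1/S genes 15 fell, 1 rose and 30 did not pass (16 and 2 adjusted over the list alone), with RRM1 of ribonucleotide reductase at -0.95 ± 0.15 and RFC2 of the clamp loader at 0.52 ± 0.14, which lost its call with length and GC trends removed (0.27). This list's camera adjusted p of 0.0396 became 0.128 without control replicate 3 (median -0.214) and 0.0666 without TRIM28 knockdown replicate 2 (median -0.155). It was 0.00855 with the length trend removed and 0.00135 with length and GC trends removed (median -0.195), and adjusted p = 0.563 with an estimated correlation. Among 37 epithelial-mesenchymal transition genes 13 fell, 4 rose and 20 did not pass (13 and 4 adjusted over the list alone). The list holds epithelial genes, such as keratins, beside mesenchymal ones, so its direction is not a direction of that transition. The matrix genes FN1 (-1.11 ± 0.14) and COL6A3 (-1.21 ± 0.15) fell, while the epithelial keratin KRT18 rose (0.56 ± 0.14). The camera adjusted p of 0.0411 became 0.111 without TRIM28 knockdown replicate 1 (median -0.044), 0.0541 without TRIM28 knockdown replicate 2 (median -0.107), 0.401 with the length trend removed and 0.0879 with limma on the deposited FPKM, and adjusted p = 0.64 with an estimated correlation.

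The list of numbered ZNF names takes zinc finger genes by symbol alone, with or without a KRAB domain, so it is not a list of KRAB zinc finger genes. Of its 351 measured genes 54 fell, 8 rose and 289 did not pass in TRIM28 knockdown (39 and 5 adjusted over the list alone). ZNF609 (-1.11 ± 0.17) and ZNF664 (-1.38 ± 0.24) were among the falls. The list as a whole did not differ from other genes (median -0.11, camera adjusted p = 0.382).

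PARP1 knockdown changed more genes, and PARP1 was followed in the named falls by RNASEH1 and TMX1. RNASEH1 (ENSG00000171865, chromosome 2, 3541430 to 3558333, minus strand), which degrades the RNA strand of RNA-DNA hybrids, fell from 27.6 ± 5.66 to 1.44 ± 0.431 CPM (SD, n = 3), 18.7-fold. TMX1 (ENSG00000139921, chromosome 14, 51240162 to 51257655, plus strand), a thioredoxin-related protein of the endoplasmic reticulum, fell from 49.3 ± 11.6 to 4.04 ± 0.721 CPM (SD, n = 3), 12.3-fold. The ubiquitin-like antiviral protein ISG15 rose 3.44-fold to 454 ± 141 CPM (SD, n = 3), and IFNB1, which encodes interferon beta, rose 3.44-fold from 1.66 ± 0.446 CPM (SD, n = 3). The histone gene H2AC7 (log2 fold change 1.88 ± 0.32), CASTOR1, a cytosolic arginine sensor (1.91 ± 0.31), and LTB, which encodes lymphotoxin beta (1.98 ± 0.36), rose as well. With length and GC trends removed, the log2 fold change was 0.59 for ISG15 against 1.78 ± 0.17, 0.70 for H2AC7, 1.18 for CASTOR1 and 0.92 for LTB, all still past the threshold.

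Other named falls in PARP1 knockdown were METTL16, an RNA methyltransferase (-2.65 ± 0.18), LPIN2, a phosphatidate phosphatase (-2.61 ± 0.26), COPB2 of the coatomer (-2.61 ± 0.19) and DIAPH1, a formin (-2.56 ± 0.16). HSP90AB3P fell as well (-2.55 ± 0.29), a pseudogene that shares sequence with HSP90AB1, so its reads are uncertain. TRAPPC5, a vesicle tethering subunit (1.90 ± 0.28), and the noncoding PPP4R3B-DT (1.86 ± 0.53) were further named rises. ARF4-AS1 rose (1.99 ± 0.55) but lost its call without PARP1 knockdown replicate 3 (0.99), and both noncoding genes and COPB2 overlap a tested gene on the opposite strand. RNASEH1 and H2AC7 overlap tested genes on their own strand, so their reads are uncertain.

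In PARP1 knockdown 8042 of 13562 genes passed, 3681 higher and 4361 lower, with 996 rising and 2547 falling at least 2-fold. The split was 2024 higher and 5803 lower with library totals in place of TMM factors, and 2140 and 4607 with limma on the deposited FPKM. Across genes, Spearman's rho of fold change was -0.428 with exon length and 0.509 with GC content, and medians ran from 0.65 in the shortest length class to -0.67 in the longest. The count stayed between 6862 and 8295 when single libraries were left out. With length and GC trends removed, 52 of 129 named fold changes in PARP1 knockdown moved by more than 1.5-fold, 15 lost their calls and 7 turned sign. Besides ISG15, H2AC7, CASTOR1 and LTB, given above, the moved log2 fold changes among those quoted for PARP1 knockdown, all with calls under both settings, were as follows. Values with both trends removed were -2.01 for METTL16, -1.82 for COPB2, -1.68 for VLDLR, -1.77 for ERAP1, -1.57 for DHX9, -1.56 for NCL and -1.27 for HNRNPU. They were -1.10 for PARP9 and CANX, -1.08 for HSPD1, -1.04 for MYOF, -1.03 for CRIM1, -1.01 for THBS1 and -1.0 for BUB1 and HSPA5. FN1 and CDH6 stood at -0.95, DTX3L at -0.93, NDUFS1 at -0.86 and RPL7L1 at -0.24, RPS2 at 0.58 and NTHL1 at 0.37, and RHOB, which moved away from 0, at -0.96.

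**Figure D2:**
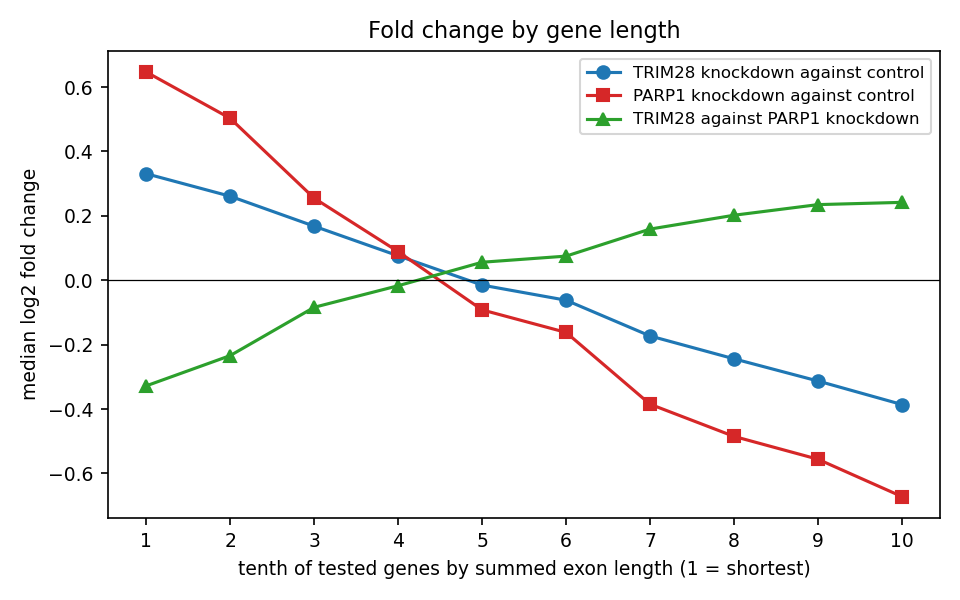
Median log2 fold change in 10 equal classes of the 13562 tested genes ordered by summed exon length, for the 3 comparisons. In PARP1 knockdown the medians ran from 0.65 in the shortest genes to -0.67 in the longest, and in TRIM28 knockdown from 0.33 to -0.39.

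Ribosomal protein genes rose in PARP1 knockdown, 76 of 81 higher, 1 lower and 4 not passing (78 and 1 adjusted over the list alone), with RPL18 at 1.19 ± 0.15 and RPS2 at 1.17 ± 0.15. The member that fell, RPL7L1, a paralog of RPL7, went from 257 ± 16.4 to 128 ± 14.0 CPM (SD, n = 3). The list median was 0.91 (camera adjusted p = 1.6e-19, and adjusted p = 0.497 with an estimated correlation). Of 42 oxidative phosphorylation genes 35 rose, 3 fell and 4 did not pass (36 and 3 adjusted over the list alone). The complex I subunits NDUFS8 (1.35 ± 0.17) and NDUFA2 (1.22 ± 0.15) rose and NDUFS1 (-1.73 ± 0.17) fell, and the list had a camera adjusted p of 9.49e-09, with adjusted p = 0.497 with an estimated correlation. Histone genes had 42 of 54 members higher and 12 not passing (43 higher adjusted over the list alone), among them H2AJ (1.17 ± 0.15). Their median was 0.92 (camera adjusted p = 1.18e-07, and adjusted p = 0.497 with an estimated correlation). It was 0.38 with the length trend removed (camera adjusted p = 0.0154) and 0.23 with length and GC trends removed (camera adjusted p = 0.152). In every comparison here, histone counts cover only transcripts captured in polyadenylated RNA, and a difference in that capture was not tested. The group means of the ribosomal share and of the length slope, given above, moved with these lists.

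Of the interferon-stimulated genes, 18 of 45 were higher, 9 lower and 18 did not pass in PARP1 knockdown (18 and 9 adjusted over the list alone). OASL rose from 245 ± 9.57 to 696 ± 80.5 CPM (SD, n = 3) and IFI27 by a log2 fold change of 1.75 ± 0.16, while PARP9 (-1.93 ± 0.29) and DTX3L (-1.59 ± 0.26) fell. The list's median was 0.27 (camera adjusted p = 0.0232, and adjusted p = 0.519 with an estimated correlation). Without control replicate 3, the median was 0.18 and the adjusted p 0.119, and the median was -0.06 with library totals in place of TMM factors and -0.02 with limma on the deposited FPKM. The call also ended with limma on median-ratio (0.084), TMM-rescaled (0.0727) or quantile-normalized FPKM (0.0675). Genes of antigen presentation had 13 of 19 members higher, 3 lower and 3 not passing (13 and 3 adjusted over the list alone). The immunoproteasome subunits PSMB9 (1.26 ± 0.16) and PSMB8 (1.01 ± 0.14) and the class I gene HLA-F (1.16 ± 0.15) rose, whereas the peptide trimming enzyme ERAP1 (-2.54 ± 0.28) and CD274, which encodes PD-L1 (-1.46 ± 0.22), fell. That list's camera adjusted p was 0.0255, and 0.0185 with the length trend removed. It was 0.167 with length and GC trends removed and 0.538 with quantile-normalized FPKM, and adjusted p = 0.497 with an estimated correlation.

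Of 37 epithelial-mesenchymal transition genes 19 fell, 4 rose and 14 did not pass in PARP1 knockdown (20 and 4 adjusted over the list alone), with fibronectin FN1 down from 4487 to 1241 CPM (-1.85 ± 0.14), COL6A3 at -2.04 ± 0.15 and THBS1 at -1.81 ± 0.14. The keratin genes KRT18 (0.93 ± 0.14) and KRT8 (0.75 ± 0.13) rose. The median of this list, which mixes epithelial and mesenchymal genes, was -0.43 (camera adjusted p = 0.00107, and adjusted p = 0.497 with an estimated correlation). Of 23 YAP/TAZ target genes 16 fell, 3 rose and 4 did not pass (16 and 3 adjusted over the list alone), including CRIM1 (-1.64 ± 0.16) and MYOF (-1.79 ± 0.19). Their median was -0.65 (camera adjusted p = 0.0128, and adjusted p = 0.497 with an estimated correlation). Proximal tubule and renal epithelial genes had 10 of 15 members lower, 1 higher and 4 not passing (10 and 1 adjusted over the list alone), with CDH6 at -1.81 ± 0.17. The camera adjusted p of that list was 0.0232, 0.0769 with the length trend removed, 0.00392 with length and GC trends removed, and adjusted p = 0.497 with an estimated correlation.

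In PARP1 knockdown HSP90AB1, the constitutive cytosolic HSP90, went from 2386 to 420 CPM (-2.50 ± 0.16), and the mitochondrial chaperonin HSPD1 fell by 1.86 on the log2 scale (SE 0.16). Of 18 heat shock genes 10 fell, 1 rose and 7 did not pass (10 and 1 adjusted over the list alone), with a camera adjusted p of 0.00725, and adjusted p = 0.497 with an estimated correlation. Of the unfolded protein response genes, 14 of 23 were lower, 5 higher and 4 did not pass (15 and 6 adjusted over the list alone). The endoplasmic reticulum chaperones CANX (-2.01 ± 0.16) and HSPA5 (-1.64 ± 0.16) fell, while the cochaperone gene CRELD2 rose (0.78 ± 0.13). Their camera adjusted p was 0.0255, and 0.036 with the length trend removed. It was 0.121 with length and GC trends removed and 0.0905 with limma on the deposited FPKM, and adjusted p = 0.497 with an estimated correlation. Of 30 TRIM28 partner and heterochromatin genes 21 fell, 2 rose and 7 did not pass (21 and 2 adjusted over the list alone), with CHD3 at -1.93 ± 0.15, MORC2 at -2.07 ± 0.18 and the heterochromatin protein gene CBX1 at -1.83 ± 0.17. The camera adjusted p was 0.000161, and adjusted p = 0.497 with an estimated correlation.

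Cell cycle, hypoxia and MYC target lists lay close to the threshold in PARP1 knockdown. Of 49 mitosis and G2/M genes 26 fell, 8 rose and 15 did not pass (26 and 8 adjusted over the list alone), with the spindle factor TPX2 at -1.85 ± 0.16 and the checkpoint kinase BUB1 at -1.74 ± 0.18. The camera adjusted p of 0.0431 became 0.0549 without control replicate 1 (median -0.499) and 0.0609 without PARP1 knockdown replicate 1 (median -0.565). It was 0.0166 with the length trend removed (median -0.408), 0.226 with length and GC trends removed (median -0.202), and adjusted p = 0.547 with an estimated correlation. Of 38 HIF target genes, which 786-O cells express through HIF-2, 18 fell, 6 rose and 14 did not pass (18 and 6 adjusted over the list alone). EPAS1, which encodes HIF-2 alpha, fell by 1.66 (SE 0.17), VLDLR by 2.60 (SE 0.22) and the cyclin gene CCND1 by 1.34 (SE 0.15) on the log2 scale. The HIF list's camera adjusted p of 0.0447 became 0.121 without control replicate 3, 0.0758 without PARP1 knockdown replicate 2, 0.0706 without PARP1 knockdown replicate 3, 0.0548 without TRIM28 knockdown replicate 2, 0.0568 without TRIM28 knockdown replicate 3 and 0.0769 with the length trend removed, and adjusted p = 0.598 with an estimated correlation. Of 33 MYC target genes 16 fell, 11 rose and 6 did not pass (17 and 11 adjusted over the list alone). Nucleolin, NCL, stood at -2.27 ± 0.18 and NME1 at 1.05 ± 0.15. The MYC list's camera adjusted p was 0.0472, and 0.0609 without PARP1 knockdown replicate 1 (median -0.621). It was 0.0537 without PARP1 knockdown replicate 3 (median -0.208) and 0.0539 without TRIM28 knockdown replicate 2 or 3 (median -0.257 in each). It was 0.322 with the length trend removed, 0.0431 with length and GC trends removed and 0.313 with limma on the deposited FPKM, and adjusted p = 0.497 with an estimated correlation.

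Repair and damage response lists, chosen because of what PARP1 does, did not move as a whole. Of 22 base excision and single-strand break repair genes 6 rose, 5 fell and 11 did not pass in PARP1 knockdown (6 and 5 adjusted over the list alone; camera adjusted p = 0.638). Their median was 0.17, their mean -0.02 and the direction of the camera test upward. The glycosylase NTHL1 rose (1.28 ± 0.17) and PARP2, the paralog of PARP1, fell (-1.57 ± 0.21). Of 30 p53 target genes, in a line whose p53 pathway was not examined here, 13 rose, 9 fell and 8 did not pass (13 and 9 adjusted over the list alone; camera adjusted p = 0.638). Their median was -0.11 and their mean -0.14, while the direction of the camera test was upward. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 34.6 to 69.2 CPM (1.00 ± 0.14) and PLK2 fell (-1.65 ± 0.16).

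**Figure D3:**
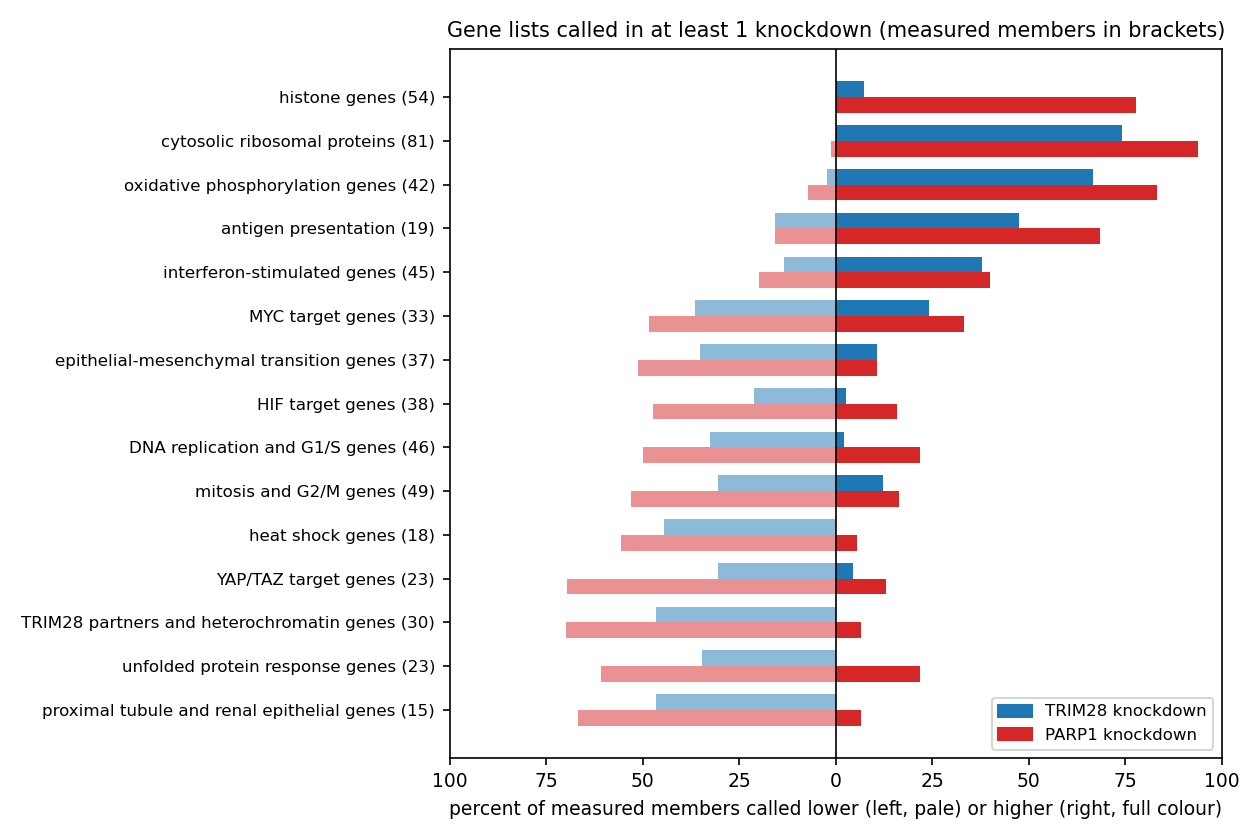
Percent of measured members of each gene list called higher (right) or lower (left, pale) in TRIM28 knockdown (blue) and PARP1 knockdown (red) against control, for the lists called by camera in at least 1 of them; measured members are in brackets. Of 81 cytosolic ribosomal protein genes 60 rose in TRIM28 knockdown and 76 in PARP1 knockdown.

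In both knockdowns 3641 genes passed in the same direction, 1342 higher and 2299 lower, which is 96.6% of the TRIM28 knockdown calls and 45.3% of the PARP1 knockdown calls. IFITM1 rose in both (1.36 ± 0.18 in TRIM28 knockdown and 1.68 ± 0.18 in PARP1 knockdown), as did IFI27. HNRNPU fell in both (-1.70 ± 0.15 and -2.02 ± 0.15), as did DHX9 (-1.68 ± 0.19 and -2.26 ± 0.20) and CHRDL1 (-1.75 ± 0.17 and -2.02 ± 0.17). Independent lists of these sizes would share 378 genes higher and 763 lower. Because both comparisons use the same 3 control libraries, all 9 libraries were simulated as unchanged groups that share simulated controls. The 20 simulations shared 0 calls by edgeR. A mean of 121 genes had an unadjusted p below 0.05 in both and in the same direction, against 5129 observed. Fold changes correlated across genes at r = 0.847, against 0.455 in those simulations. Their covariance was 0.394, against 0.0356 simulated, a difference of 0.359. The simulations drew genes independently, without the length trends by which the real control replicates differ. Their values may therefore understate what shared controls give. With 3 controls no split leaves 2 on each side, so part of the excess over independent lists may come from the shared controls. The labels do not settle whether the controls were transfected, so a transfection effect is not separated from these shared changes. The shared count was 1501 without control replicate 1, 1816 without control replicate 2 and 2075 without TRIM28 knockdown replicate 2, and the split was 1429 higher and 1311 lower with length and GC trends removed and 430 and 2816 with library totals.

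Only 8 of the tested genes passed in opposite directions. CFL1, the actin-severing protein cofilin, rose from 1467 ± 181 CPM in control to 2003 ± 57.8 CPM in TRIM28 knockdown and fell to 528 ± 33.9 CPM in PARP1 knockdown (SD, n = 3). LIMK1, the kinase that phosphorylates cofilin, did the reverse (-0.95 ± 0.14 and 0.54 ± 0.14). ARPC1A, a subunit of the Arp2/3 complex, moved with CFL1 (0.40 ± 0.13 and -0.57 ± 0.13), as did MVD of cholesterol synthesis (0.39 ± 0.15 and -0.76 ± 0.15) and the GTPase RHOB (0.43 ± 0.13 and -0.34 ± 0.13). TSPAN4, a tetraspanin, moved with LIMK1 (-0.62 ± 0.15 and 1.15 ± 0.15), as did CCDC74A (-0.78 ± 0.23 and 0.80 ± 0.22), and the last was TRIM28. The rises of CFL1, ARPC1A, MVD and RHOB in TRIM28 knockdown lost their calls without control replicate 1 (0.41, 0.38, 0.31 and 0.43) or control replicate 2 (0.43, 0.40, 0.39 and 0.42). CCDC74A lost its TRIM28 knockdown call without TRIM28 knockdown replicate 1 (-0.63), and RHOB its PARP1 knockdown call in 7 of the 9 fits that left out 1 library (-0.33 to -0.25). ARPC1A and MVD also lost theirs without TRIM28 knockdown replicate 1 (0.40 and 0.41) or 2 (0.42 and 0.40), MVD and RHOB without replicate 3 (0.42 and 0.40), and MVD without PARP1 knockdown replicate 2 (0.39). With length and GC trends removed, the TRIM28 knockdown rises of ARPC1A (0.24), MVD (0.24) and RHOB (0.10) and the PARP1 knockdown rise of CCDC74A (0.25) lost their calls and TRIM28 in PARP1 knockdown turned to -0.22, while CFL1, LIMK1 and TSPAN4 passed in opposite directions under that setting too. CFL1 shares sequence with pseudogenes and overlaps a tested gene on the opposite strand, and ARPC1A overlaps one on its own strand, so their reads are uncertain.

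**Figure D4:**
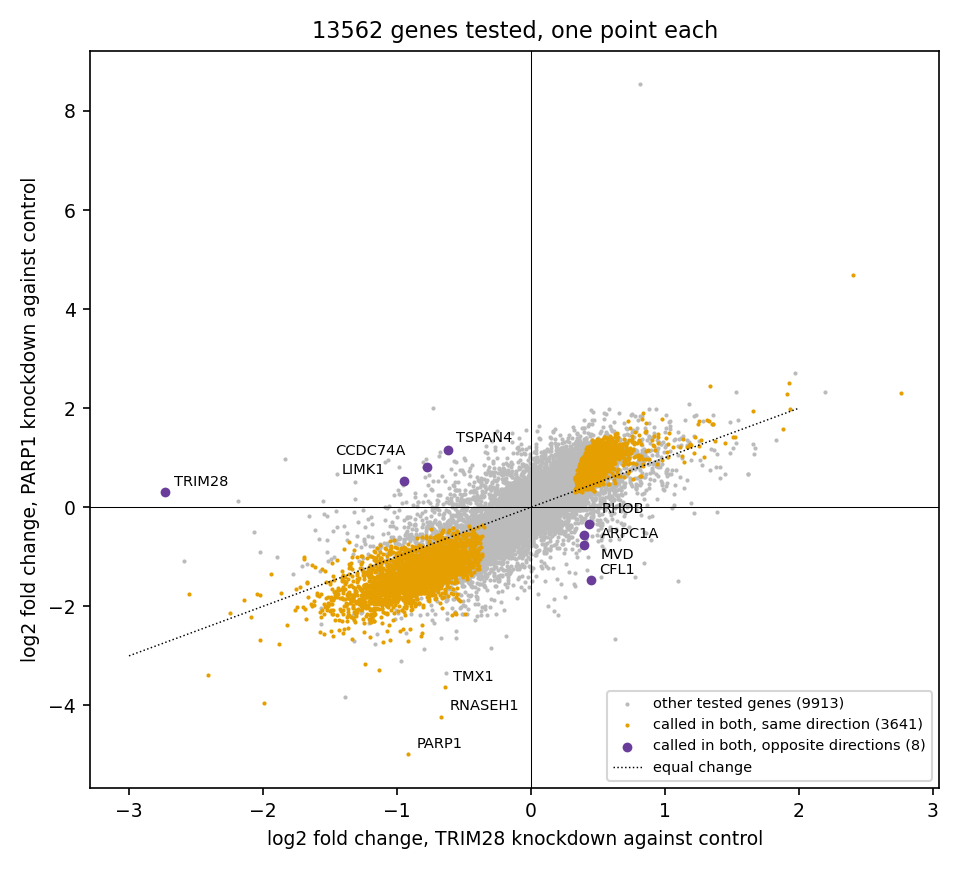
Log2 fold change of each of the 13562 tested genes in PARP1 knockdown (vertical) against that in TRIM28 knockdown (horizontal), both relative to control; orange points passed in both in the same direction (3641), purple points in opposite directions (8), and the dotted line marks equal change. RNASEH1 and TMX1 lie far below that line.

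Directly compared, TRIM28 knockdown and PARP1 knockdown differed in both targets, in RNASEH1 and TMX1 and in CFL1. RNASEH1 stood at 17.4 ± 1.48 CPM in TRIM28 knockdown against 1.44 ± 0.431 CPM in PARP1 knockdown (SD, n = 3), 11.8-fold, and TMX1 at 31.6 ± 3.67 against 4.04 ± 0.721 CPM (SD, n = 3), 7.91-fold. CFL1 was higher in TRIM28 knockdown (log2 difference 1.92 ± 0.13), as was MAGEA12, a cancer-testis antigen gene with near-identical relatives (2.38 ± 0.43), and TSPAN4 was lower (-1.77 ± 0.15). Lower as well were PAGE1, another cancer-testis gene (-1.79 ± 0.49), the noncoding PSORS1C3, which overlaps POU5F1 on its own strand, so that its reads are uncertain (-2.01 ± 0.59), and the pseudogene RPS20P23 (-1.82 ± 0.61). All 3 lost their calls without TRIM28 knockdown replicate 1 (-1.39, -1.52 and -1.47), and the last 2 also without TRIM28 knockdown replicate 2 (-1.77 and -1.78) or PARP1 knockdown replicate 3 (-1.84 and -1.52). PAGE1, PSORS1C3 and RPS20P23 held 0.476, 0.295 and 0.262 CPM in TRIM28 knockdown and 1.62, 1.27 and 0.968 CPM in PARP1 knockdown. MAGEA12 held 2.97 CPM in TRIM28 knockdown and 0.541 CPM in PARP1 knockdown, so the differences of these genes rest on few reads.

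**Figure D5:**
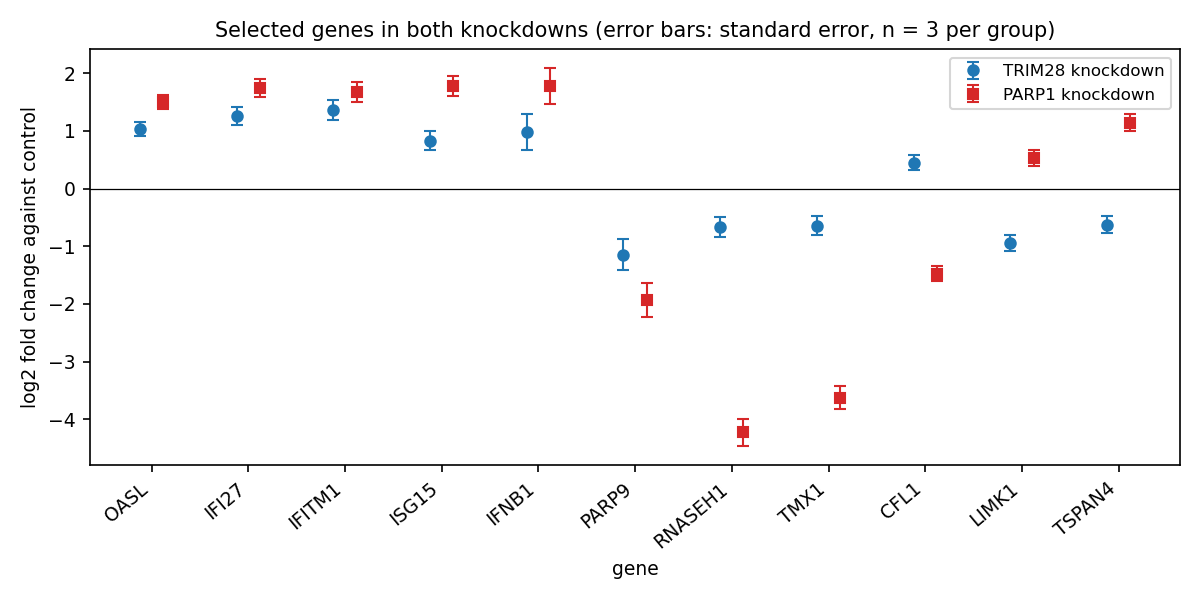
Log2 fold change against control of 11 genes in TRIM28 knockdown (blue circles) and PARP1 knockdown (red squares), with standard errors over 3 libraries per group. OASL, IFI27, IFITM1, ISG15 and IFNB1 lie above 0 in both knockdowns and PARP9 below 0, while CFL1, LIMK1 and TSPAN4 lie on opposite sides.

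Between the knockdowns 3407 of 13562 genes differed, 1795 higher in TRIM28 knockdown and 1612 lower. The split was 2350 and 640 with library totals in place of TMM factors and 1720 and 672 with limma on the deposited FPKM. The count was 1654 without TRIM28 knockdown replicate 1, 2254 without TRIM28 knockdown replicate 3, 2149 without PARP1 knockdown replicate 2 and 1712 without PARP1 knockdown replicate 3. It was 2027 with length and GC trends removed.

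Of 81 ribosomal protein genes 45 were lower in TRIM28 knockdown than in PARP1 knockdown, 1 was higher and 35 did not pass (60 and 1 adjusted over the list alone), with RPS16 at -0.84 ± 0.15 (camera adjusted p = 3.05e-13, 0.081 with quantile-normalized FPKM, and adjusted p = 0.554 with an estimated correlation). Histone genes were lower too, 28 of 54 and 26 not passing (40 lower adjusted over the list alone; camera adjusted p = 8.75e-12, and adjusted p = 0.554 with an estimated correlation). Of 42 oxidative phosphorylation genes 23 were lower, 3 higher and 16 did not pass (25 and 3 adjusted over the list alone), with NDUFS8 at -0.83 ± 0.17 (camera adjusted p = 3.8e-05, 0.166 with quantile-normalized FPKM, and adjusted p = 0.554 with an estimated correlation). Genes encoded by the mitochondrial genome went the other way: 10 of 13 were higher in TRIM28 knockdown and 3 did not pass (10 higher adjusted over the list alone), among them MT-ND5 (0.76 ± 0.16) and MT-ND4 (0.61 ± 0.14). That list's camera adjusted p was 8.23e-05, and adjusted p = 0.554 with an estimated correlation. Against control, in PARP1 knockdown, the mitochondrially encoded list had 8 members lower, 1 higher and 4 not passing (10 and 1 adjusted over the list alone), with a camera adjusted p of 0.254 that became 0.000347 with the length trend removed.

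Of 37 epithelial-mesenchymal transition genes 14 were higher in TRIM28 knockdown than in PARP1 knockdown, 1 lower and 22 did not pass (16 and 2 adjusted over the list alone). The tight junction gene CLDN1, an epithelial member, stood at 1.21 ± 0.15 and the integrin gene ITGB3 at 0.91 ± 0.15. The list's camera adjusted p was 0.000105, and adjusted p = 0.554 with an estimated correlation. It mixes epithelial and mesenchymal genes, so this call gives no direction of that transition. YAP/TAZ target genes had 9 of 23 members higher, 1 lower and 13 not passing (11 and 1 adjusted over the list alone), among them CCN2 (0.83 ± 0.16; camera adjusted p = 0.0104, and adjusted p = 0.554 with an estimated correlation). Of 38 HIF target genes 10 were higher, 1 lower and 27 did not pass (10 and 1 adjusted over the list alone), with VLDLR at 1.78 ± 0.23 and the glucose transporter SLC2A3 at 1.13 ± 0.17 (camera adjusted p = 0.0109, and adjusted p = 0.554 with an estimated correlation). The cancer-testis list had 7 measured members, 3 higher, 1 lower and 3 not passing (4 and 1 adjusted over the list alone), with the near-identical MAGEA3 (1.03 ± 0.15) and MAGEA6 (1.14 ± 0.20), whose reads are uncertain (camera adjusted p = 0.00899, 0.0689 with limma on the deposited FPKM, and adjusted p = 0.554 with an estimated correlation). Interferon-stimulated genes had 2 of 45 members higher, 7 lower and 36 not passing (2 and 7 adjusted over the list alone; camera adjusted p = 0.571), with a median of -0.04 and a mean of 0.01, MX2 higher (0.69 ± 0.21) and ISG15 lower (-0.95 ± 0.17) in TRIM28 knockdown.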

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

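Among the alternatives here, library totals without TMM factors and the removal of length or of length and GC trends were chosen only after the result was seen. Of 5839, 412 and 22 values of named genes under alternatives, in that order, the first kept direction and side of the threshold, the second kept direction alone and the third reversed. For list calls these numbers were 559, 90 and 2. The cause was not tested unless stated. The settings on FPKM use limma and the deposited scale in place of edgeR on counts, so their starting point is limma on log2(FPKM + 1), which gave 2703 genes in TRIM28 knockdown, 6747 in PARP1 knockdown, 2392 between them and 2633 in both. The number of genes changed in TRIM28 knockdown, 3768 by edgeR and 2703 by that fit, was 2353 and 2250 with pseudocounts of 0.1 and 0.01 on FPKM, 1069 without a filter on FPKM, 1744 with a mean FPKM of at least 2, 2441 with quantile-normalized FPKM and, by edgeR, 811 at 2-fold. For genes changed in both knockdowns, 3641 by edgeR and 2633 by limma, the same settings gave 2295, 2198, 1040, 1703, 2357 and 731. In PARP1 knockdown, with 8042 by edgeR and 6747 by limma, a mean FPKM of at least 2 gave 4785 by limma and the 2-fold limit 3543 by edgeR. Between the knockdowns, with 3407 by edgeR and 2392 by limma, limma gave 63 without a filter on FPKM and 2269 with quantile-normalized FPKM, and edgeR gave 2027 with length and GC trends removed and 333 at 2-fold. The filter of 2 tests fewer genes and the 2-fold limit passes fewer by construction. Leaving out 1 library gave 1537 to 4935 genes in TRIM28 knockdown, 6862 to 8295 in PARP1 knockdown, 1654 to 4714 between them and 1501 to 4730 in both, the lowest without control replicate 1 in all but the direct comparison, where it was without TRIM28 knockdown replicate 1. Lists called, 9, 14 and 8, were 0, 0 and 0 by camera with an estimated correlation, where 3, 3 and 0 had an unadjusted p below 0.05. By fry, which does not compare a list with other genes, 14 lists passed in TRIM28 knockdown and 25 in PARP1 knockdown. Over fits without 1 library the lists called were 6 to 13 in TRIM28 knockdown, 12 to 14 in PARP1 knockdown and 8 to 13 between them.

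TRIM28 in PARP1 knockdown reversed to -0.013 with limma on deposited FPKM at each pseudocount, filter and trend setting, to -0.011 with library totals, to -0.15 with quantile-normalized FPKM and to -0.22 with length and GC trends removed. With both trends removed, TK1 (-0.22), E2F1 (-0.073), GADD45B (-0.02), FJX1 (-0.37), H2AX (-0.23) and HSPB1 (-0.38) reversed in PARP1 knockdown, and GADD45B (0.013) and H2AX (0.13) between the knockdowns. Quantile normalization reversed HSPB1 (-0.037), AJUBA (-0.14) and MT-ND3 (-0.33) in PARP1 knockdown, and removing the length trend reversed MT-ND3 (-0.20). The histone median in TRIM28 knockdown reversed to -0.046 with the length trend removed and to -0.12 with both. Lists not called before also passed by camera at the preset correlation with both trends removed. Among them, glycolysis enzymes were higher in TRIM28 knockdown (camera adjusted p = 0.02) and PARP1 knockdown (0.0428). In PARP1 knockdown DNA replication and G1/S genes (0.0105) and cancer-testis genes (0.0105) were lower. The median of all genes shifted by -0.15, -0.31 and 0.16 in TRIM28 knockdown, PARP1 knockdown and between them with limma on deposited FPKM, and between them by 0.17 with library totals. In PARP1 knockdown it shifted by -0.13 with TMM-rescaled FPKM, 0.18 with the length trend removed and 0.22 with both, and between the knockdowns by -0.13 with both. The replicate block gave 4085, 8071, 3662 and 3942 genes in TRIM28 knockdown, PARP1 knockdown, between them and in both. It ended 1 list call, epithelial-mesenchymal transition genes in TRIM28 knockdown (camera adjusted p = 0.0524). Deviations of same-numbered libraries correlated at -0.08 to 0.14, with 2 of 9 pairs over 0.1, and 1 library correlated best with its own number, so the numbers do not pair the libraries. With simulated data, where 200 genes changed, edgeR recovered 23.9% of 1.5-fold changes in TRIM28 knockdown. The real comparisons with control called 3768 and 8042 genes, which makes the adjusted threshold less strict, so this share does not carry over to them. Small changes at this depth and number of libraries can still be missed.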

Other observations

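The tests in this part were chosen only after the result was seen, except that on thinned counts. Also quoted here are planned settings: fits without 1 library, limma on deposited FPKM and, for the fixed gene lists, camera with either correlation. Of 296 KEGG pathways tested by camera, 3 were called in TRIM28 knockdown, 4 in PARP1 knockdown and 2 between the knockdowns, and 1, 2 and 1 of these were also called with length and GC trends removed. Oxidative phosphorylation was higher in both knockdowns (camera adjusted p = 4.98e-07 and 5.04e-05, 0.00015 and 0.00527 with both trends removed, and adjusted p = 0.495 and 0.527 with an estimated correlation). The systemic lupus erythematosus pathway, which holds many histone genes, was higher in PARP1 knockdown than in control (camera adjusted p = 0.00164, 0.181 with both trends removed, and adjusted p = 0.527 with an estimated correlation). It was lower in TRIM28 knockdown than in PARP1 knockdown (camera adjusted p = 8.56e-05, 0.0196 with both trends removed, and adjusted p = 0.712 with an estimated correlation). Genes of the adherens junction, which joins neighbouring epithelial cells, fell in both knockdowns. In TRIM28 knockdown 31 of 70 fell and 3 rose (median log2 fold change -0.41, camera adjusted p = 0.000756, and adjusted p = 0.495 with an estimated correlation), and in PARP1 knockdown 43 fell and 7 rose (median -0.88, camera adjusted p = 0.000255, and adjusted p = 0.527 with an estimated correlation). VCL, which encodes vinculin, stood at -1.35 ± 0.16 and -1.94 ± 0.16 (SE, n = 3 per group), and in PARP1 knockdown the polarity gene PARD3 at -1.74 ± 0.16 and the receptor gene EGFR at -1.52 ± 0.16 (SE, n = 3 per group). With length and GC trends removed the adjusted p was 0.0976 in TRIM28 knockdown and 0.0364 in PARP1 knockdown. Between the knockdowns 19 members were higher in TRIM28 knockdown and 3 lower (camera adjusted p = 0.00835, 0.179 with both trends removed, and adjusted p = 0.712 with an estimated correlation).

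Genes of TGF-beta signaling fell as well, 29 of 67 in TRIM28 knockdown with 4 rising (camera adjusted p = 0.014, and adjusted p = 0.495 with an estimated correlation) and 37 in PARP1 knockdown with 8 rising (camera adjusted p = 0.0389, and adjusted p = 0.527 with an estimated correlation). SP1, a transcription factor, stood at -1.49 ± 0.19 in TRIM28 knockdown and the receptor gene TGFBR2 at -1.64 ± 0.17 in PARP1 knockdown (SE, n = 3 per group). With both trends removed the adjusted p was 0.0976 and 0.0961. ENSG00000280614, a transcript of the ribosomal DNA region on chromosome 21, rose from 298.9 ± 218 CPM in control to 1584 ± 453 in TRIM28 knockdown and 7687 ± 9379 in PARP1 knockdown (SD, n = 3). Its log2 fold changes were 2.41 ± 0.54 (adjusted p = 0.00194) and 4.69 ± 0.59 (adjusted p = 3.66e-07, SE, n = 3 per group, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). PARP1 knockdown replicate 2 held 18460 CPM against 1370 and 3228 in the other replicates, and without it the PARP1 knockdown mean was 2299 CPM and the log2 fold change 2.94 (adjusted p = 4.09e-07). Without control replicate 3 the control mean was 174 CPM and the log2 fold changes 3.21 and 5.50. This transcript held 201, 548 and 1370 CPM in control replicates 1 and 3 and PARP1 knockdown replicate 1. The chosen set of transcripts of the region, summed for the shares given above, took 0.393%, 0.339% and 0.702% of counts there. The rise of this transcript therefore does not give the size of the set's change. The libraries were made from polyadenylated RNA, and whether these reads reflect transcription was not tested.

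Splits of the libraries tested whether other groupings call as many genes. For TRIM28 knockdown, PARP1 knockdown and the direct comparison, 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 3768, 8042 and 3407 genes by edgeR and the highest others 0, with 1834, 1415 and 1716 genes at an unadjusted p below 0.05 against 5449, 8561 and 5013 in the real ones. For genes changed in both knockdowns, 1 of 60 groupings, the real one, gave as many as 3641, and the highest other gave 2632. The 3 other groupings with the controls as the reference group gave 2397 to 2632. The 56 others gave 0 by edgeR, with at most 955 genes at an unadjusted p below 0.05. A grouping that held the controls together as a compared group was among those 56. Because only groupings with the controls as the reference had shared calls, those 3 are the groupings left to compare with, too few to exclude chance. In these groupings, calls shared by both comparisons arose only with the controls as the common reference.

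Long, AT-rich genes were lower and short, GC-rich genes higher in both knockdowns. With every library thinned to 11963110 counts, Spearman's rho of PARP1 knockdown fold change and exon length across genes, which are not independent replicates, was -0.432, against -0.428 with all counts. The trend thus remained at equal totals. Thinning keeps each gene's expected share of its library, so rho could hardly change, and the test says nothing of what made some libraries smaller. Removing both trends left 53.5% of the TRIM28 knockdown calls and 59.9% of the PARP1 knockdown calls past the threshold in the same direction. These kept shares argue against length and GC content as the whole of the change. The remaining calls were lost, and 802 of the 8042 PARP1 knockdown calls turned sign, with 111 of them passing in the opposite direction. For those calls the result depends on the trends. Variation between libraries that the knockdowns do not set stays open: the deviation of a library from its group correlated with the difference of the other groups at a median absolute r of 0.2, on the bound set for the test. The absolute r was 0.32, 0.2 and 0.42 in control replicates 1 to 3. It was 0.04 to 0.16 in TRIM28 knockdown and 0.01 to 0.21 in PARP1 knockdown. A difference in RNA handling may therefore account for part of the pattern, and so may the knockdowns.

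RNASEH1 and TMX1 fell far in PARP1 knockdown. With both trends removed the smaller of the 2 falls was -3.22, which argues against gene length and GC content, and RNASEH1 summed with overlapping genes and copies stood at -3.28, which argues against reads moved between them. For TMX1 that sum (-3.61) added no counts to its own, so it tested nothing and reads moved to a copy stay open. A dependence on the PARP1 transcript level stays open: in TRIM28 knockdown, where PARP1 also fell, RNASEH1 stood at -0.56 ± 0.16 and TMX1 at -0.39 ± 0.11 (SE, n = 3 per group) with both trends removed. An effect of the reagent's sequence on these transcripts may be another cause, which was not tested because no reagent sequence was used here.

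Interferon-stimulated genes were called higher in both knockdowns, with members going both ways and adjusted p = 0.539 and 0.519 with an estimated correlation, and their PARP1 knockdown median turned to -0.06 with library totals and to -0.02 with limma on deposited FPKM. With both trends removed the higher camera adjusted p was 0.00595, which argues against gene length and GC content. Without control replicate 3 it was 0.119, with a median still above 0 in PARP1 knockdown (0.18), so the part of that library stays open. A response to the silencing reagents that does not depend on the target may account for the rise, and 20% of the members differed between the knockdowns, on the bound set for the test. No test here separates it from an effect of the knockdowns themselves.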
